A study of Mus musculus with 24 samples.

How the data were processed

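Gene expression was measured on arrays in conventional dendritic cells (cDC) from the spleens of 8 to 10 week old female NOD and B6 mice, 12 h after an injection of PBS or CpG-A. Per the labels' protocols, spleens were digested with collagenase, CD11c+ cells were sorted into CD8+ and CD11b+ cDC, and 5 ng of total RNA was amplified and 2.5 ug of cDNA labelled and hybridised. The deposited values are log2 expression values, made by the authors with RMA in Partek per the submitters' processing notes, which give no version. They lay between 1.92 and 14.1 over 35556 probe sets, and were used without further normalization. The labels name another array model than the whole-transcript gene array whose annotation the probe set identifiers match, so the model is left unsettled. A table pairing probe sets with the platform annotation listed 23410 of them, 21789 with a single gene symbol and 1621 with several, and 12146 were not listed and so are unnamed here. Symbols were updated by gene ID for 21698 probe sets. Only probe sets with a single symbol were used, and where a gene had more than 1 (999 genes) the probe set with the highest mean stood for it, which left 19938 genes. Genes whose value exceeded the array's own median on at least 3 of the 24 arrays were tested, 11228 in number. Array medians ran from 5.79 to 5.88, which RMA normalization brings together. The signal over background limits which genes can be tested, and the number of arrays limits the precision.

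Subset, strain and injection define 8 groups of 3 arrays, and replicate numbers come from the sample titles. In R 4.3.3 with the data.table package in version 1.17.8, limma 3.58.1 fitted a mean per group with 16 residual degrees of freedom, and 16 contrasts were tested two-sided with eBayes and its trend, with Benjamini-Hochberg adjustment within each contrast at 0.05. Of these 10 compare groups of 3 arrays, and the others are interactions of strain, subset and CpG. The shift of 36 gene and marker lists was tested with camera in limma with a preset correlation of 0.01 between genes, for lists with at least 5 measured members and adjusted over all lists of a contrast. Counts of list members past the threshold are given over all genes and adjusted over the list alone, and where only 1 count is given both were the same. Camera with an estimated correlation and fry served as alternatives. The lists, the tests, the choice of probe set and filter, the alternatives and the rule for naming genes were fixed before the data were examined. That rule allows per contrast the 10 highest and 10 lowest called genes, for a comparison of groups only where the groups of 3 did not overlap, which chance alone gives a gene with a share of 0.1. It further allows for each list up to 4 called members with the largest change and up to 2 members that did not pass with the highest mean, and always Cd8a, Itgam, Itgax, Tlr9, Ifnb1, Il1b, Ptger4, Zbtb32 and Clec4a4. A gene named for CpG may be given for the other strain or subset and in the interaction. Among the genes so allowed, those whose call ended under an alternative were left out or are given with that value, a choice made after the values were seen. Probes shared by near-identical family members, such as the Klra, Ifi200, H2bc and Apol genes, leave their assignment to a gene uncertain, and NOD variants under a probe were not tested per probe.

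The alternatives were no filter, a filter asking for 12 of the 24 arrays, the mean of a gene's probe sets, every probe set tested alone, quantile normalization, median centring of each array, eBayes without the trend, robust eBayes, array weights, a fit of only the groups compared, the replicate number as a fixed or random block (the latter with statmod 1.5.0), and each array left out in turn. Array weights measure how far an array lies from the fit and not its quality. The weight of replicate 2 of CpG-treated NOD CD8+ cDC was 12.48, against 0.15 and 0.39 for the other 2 arrays of that group, so weighted results there rest mostly on this array. Whether same-numbered arrays deviate together was checked from deviations from the group means. Of 84 same-numbered pairs of arrays 75 correlated positively, with a median of 0.14. Every pair was over 0.1 in the comparisons of CpG with PBS in NOD CD8+ (0.181 to 0.338) and NOD CD11b+ cDC (0.155 to 0.215), of NOD with B6 in CD8+ cDC under PBS (0.2 to 0.288) and CpG (0.242 to 0.544), and of the subsets in B6 (0.135 to 0.277) and NOD (0.105 to 0.178), so the numbers pair arrays there. What the numbers stand for is not stated. With the replicate number as a block these comparisons called 4945, 2103, 513, 2780, 2710 and 2772 genes, each within 1.5 times the count without it. The block ended the camera calls of the neutrophil markers between subsets in B6 (adjusted p = 0.0585) and of the IFN-inducible GTPases between subsets in NOD (adjusted p = 0.0568). With it camera passed for chemokines after CpG in NOD CD8+ cDC (adjusted p = 0.0488), NF-kB targets (0.0417) and pan-cDC markers (0.0326) between strains in CD8+ cDC under PBS, NF-kB targets there after CpG (0.0472), and B cell markers between subsets in NOD (0.0358).

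The steps were tested on simulated data for the comparison of CpG with PBS in B6 CD8+ cDC, with 11228 genes of which 200 were changed. Of 50 genes each changed by log2 2, 1, -1 and 0.5, the fit recovered 98%, 92%, 100% and 44%, with mean estimates of 2.02, 1.02, -1.04 and 0.51. Of the calls, 5.1% were unchanged genes, and a comparison with no change called 0 genes. The unadjusted p value of camera was 1.38e-15 for a list shifted by 0.5 and 0.31 for an unshifted list, and the noise-corrected slope of 1 response on another came out at 0.61 for a true 0.6. Results given a closer look are the counts of all interaction tests, the list shifts that passed in the tests of strain or subset with CpG, and, in the tests of strain with CpG, the always named genes called and the 3 called genes with the highest and the 3 with the lowest values. The search for a lone outlying array needs groups larger than 3 and was not made. No array and no value column was left out.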

Results

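Messenger RNA was measured on 24 expression arrays, each made from conventional dendritic cells (cDC) sorted from spleen. These cells take up and present antigen and come in a CD8+ and a CD11b+ subset. The mice were nonobese diabetic (NOD), a strain that develops autoimmune diabetes, or C57BL/6 (B6) controls, and had been injected 12 h earlier with PBS or with CpG-A, an oligonucleotide recognised by Toll-like receptor 9. Subset, strain and injection make 8 groups of 3 arrays. Values are deposited log2 expression values, differences are log2 differences ± the standard error from the limma fit with n = 3 arrays per group, and "rose" or "fell" is used only for adjusted p values under 0.05. For a list of genes, the counts of members that passed are followed by the median difference and by the adjusted p of the camera set test. Where that passed, the adjusted p with an estimated correlation between genes comes next, and a shift that passed only in the first rests on the preset correlation of 0.01. The mean correlation of an array with its own group ran from 0.951 to 0.988. The number of arrays limits the precision. Labels do not say whether the 3 replicates of a group came from separate animals, so the p values measure only the spread between these samples, which may be technical. The first principal component held 47.9% of the variance and the second 24.9%, and on the first the 3 arrays of CpG-treated NOD CD8+ cDC lay at 53.5, 32.5 and 17.4.

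**Figure D1:**
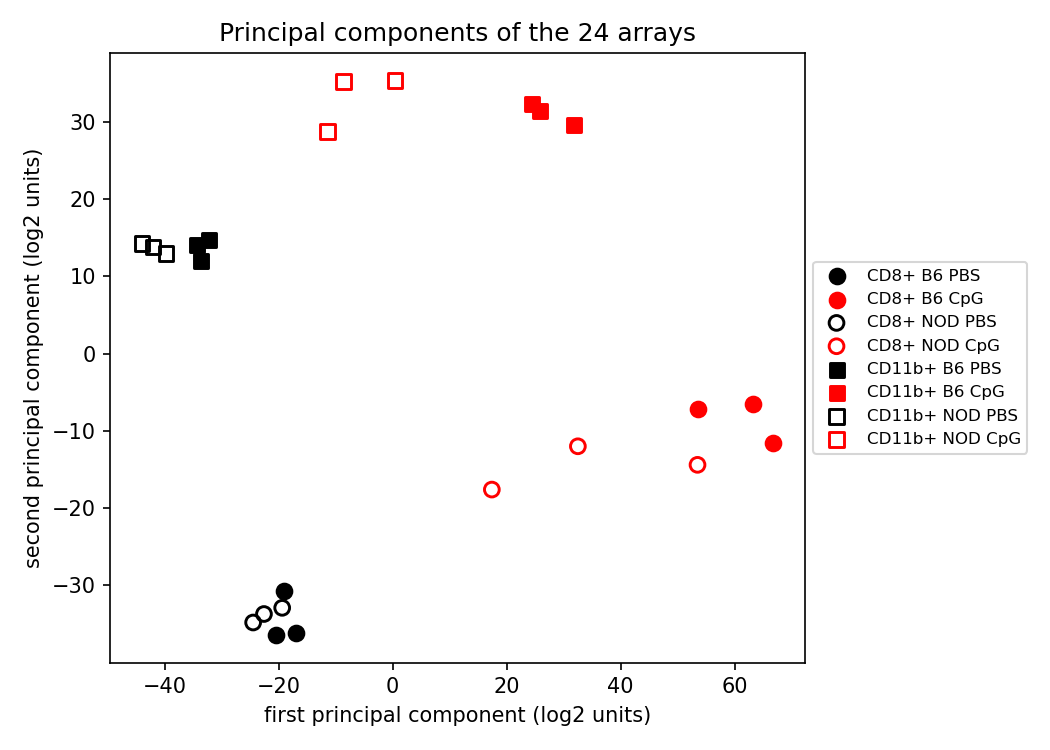
Principal components of the 24 arrays over 11228 genes, with the first component (47.9% of variance) on the x axis and the second (24.9%) on the y axis, both in log2 units. Each point is 1 array, colour gives the treatment, marker shape the subset, and open symbols are NOD. CpG arrays lie to the right of the PBS arrays of the same subset and strain. NOD CpG arrays lie to the left of B6 CpG arrays of the same subset, replicate 1 of NOD CD8+ cDC by little (53.5 against 53.6 for replicate 3 of B6).

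The comparison of CD8+ with CD11b+ cDC under PBS checks the sort labels against genes known to mark each subset. In B6 mice Cd8a, which gives the CD8+ subset its name, was higher in CD8+ cDC by 4.47 ± 0.26, the chemokine receptor gene Xcr1 by 4.10 ± 0.22 and the scavenger receptor gene Cd36 by 3.60 ± 0.27. Itgam, which encodes CD11b, was lower, at -3.94 ± 0.24, and Clec4a4, which encodes the inhibitory lectin DCIR2, at -4.33 ± 0.22. Of the cDC1 markers, the genes typical of CD8+ cDC, 21 of 22 measured genes were higher (22 higher adjusted over the list alone, median 2.81, adjusted p = 5.11e-35 and 0.00712). The transcription factor gene Batf3 did not pass (0.21, adjusted p = 0.143). Among the cDC2 markers, typical of CD11b+ cDC, 16 of 18 were lower and 1 higher (median -1.64, adjusted p = 2.31e-15 and 0.00712). NOD cells differed in the same way for Cd8a (5.62 ± 0.26), Xcr1 (4.43 ± 0.22), the integrin gene Itgae (4.49 ± 0.26), Itgam (-3.92 ± 0.24) and Clec4a4 (-3.95 ± 0.22). Among NOD cDC1 markers 20 of 22 were higher (median 2.73, adjusted p = 1.42e-32 and 0.0183), and among cDC2 markers 15 of 18 were lower and 1 higher (median -1.52, adjusted p = 2.89e-12 and 0.0194). MHC class I peptide loading genes were also higher in the CD8+ subset. In B6 12 of 15 were higher (median 0.45, adjusted p = 6.62e-07 and 0.0454) and in NOD 11 of 15 were higher (median 0.47, adjusted p = 9.91e-07 and 0.035), led by the transcriptional activator gene Nlrc5 at 0.80 ± 0.14 and 1.48 ± 0.14. Interferon-stimulated genes were lower in unstimulated CD8+ cDC. In B6 23 of 44 were lower and 3 higher (median -0.46, adjusted p = 1.63e-09 and 0.474), with the chaperone gene Rtp4 at -3.63 ± 0.24 and the antiviral Ifit3 at -3.41 ± 0.25. In NOD 18 of 44 were lower and 6 higher (median -0.26, adjusted p = 0.000333 and 0.63). Toll-like receptor genes went both ways, with Tlr3 higher (2.87 and 2.99) and Tlr7 lower (-2.87 and -2.84), and Tlr9, the receptor for CpG, was a little lower in NOD CD8+ cDC (-0.42 ± 0.11). Interleukin-1 and inflammasome genes were lower in B6 CD8+ cDC for 10 of 22 (median -0.42, adjusted p = 0.0027 and 0.239), among them the inflammasome sensor Nlrc4 (-1.91). Chemokine genes were higher in NOD CD8+ cDC, where 7 of 17 were higher and 3 lower (median 0.40, adjusted p = 0.00554 and 0.255), and pDC markers likewise, where 7 of 9 were higher (median 0.65, adjusted p = 3.01e-05 and 0.134). Neutrophil markers were lower in CD8+ cDC of NOD mice, where 3 of 5 were lower (4 lower adjusted over the list alone, median -1.20, adjusted p = 0.000296 and 0.0195). Across genes the limma fit called 2442 in B6 (1074 higher and 1368 lower in CD8+ cDC) and 2448 in NOD (1192 and 1256), of which 807 were higher and 906 lower in both. If the calls were independent, 114 and 153 would be shared. Median centring turned the split in B6 into 1325 higher and 1251 lower.

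The next 4 comparisons ask what CpG injection does to each subset in each strain. In CD8+ cDC of B6 mice the antiviral genes Rsad2 (5.76 ± 0.25), Ifit1 (5.75 ± 0.23), Ifit3 (5.72 ± 0.25) and Ifit2 (5.26 ± 0.21) rose most among interferon-stimulated genes. Of the type I IFN-stimulated genes 43 of 44 measured genes rose (median 3.17, adjusted p = 3.54e-39 and 0.11), the exception being Pnpt1 (0.16, adjusted p = 0.348). Of the IFN-inducible GTPases and IFN-gamma-response genes 10 of 11 rose and 1 fell (median 2.49, adjusted p = 1.66e-07 and 0.119), with the immunity-related GTPase gene Iigp1 at 3.82 ± 0.17 and the guanylate-binding protein gene Gbp5 at 3.46 ± 0.20. Other large increases were Sct, which encodes the hormone secretin (5.74 ± 0.25), AA467197, the mouse counterpart of NMES1 (6.28 ± 0.28), and the schlafen genes Slfn4 (5.42 ± 0.25) and Slfn1 (5.30 ± 0.21). Among DC maturation and co-stimulation genes 19 of 22 rose and 1 fell (median 2.01, adjusted p = 6.89e-11 and 0.156), including Cd200 (3.18 ± 0.20), the PD-L1 gene Cd274 (2.87 ± 0.19) and the actin-bundling gene Fscn1 (2.59 ± 0.21). NF-kB targets rose for 17 of 25 (2 fell, median 0.80, adjusted p = 4.88e-07 and 0.156), with the cytokine gene Il6 at 4.21 ± 0.21, whereas Il1b, the gene of interleukin-1 beta, fell (-1.90 ± 0.24). Of the cytokines acting on lymphocytes 7 of 12 rose and 4 fell (median 0.62), with Il27 at 2.83 ± 0.18. Chemokine genes rose for 8 of 17 (2 fell, median 0.53), led by Cxcl10, which attracts activated T cells (4.28 ± 0.28). MHC class I peptide loading rose for 11 of 15 (2 fell, median 0.70, adjusted p = 2.06e-05 and 0.119). Apoptosis and necroptosis genes rose for 10 of 16 (2 fell, median 0.58, adjusted p = 0.00478 and 0.256), among them the death receptor gene Fas (2.77 ± 0.26).

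Many genes that mark the resting CD8+ subset fell in B6 mice. Of the cDC1 markers 19 of 22 fell and 1 rose (median -1.75, adjusted p = 7.43e-06 and 0.338), with Hepacam2 at -4.15 ± 0.17 and Cd36 at -2.68 ± 0.27, although Cd8a itself did not pass (0.09). Itgax, which encodes CD11c, fell (-2.04 ± 0.18), and among the pan-cDC markers 4 of 8 fell and 3 rose (median -0.42, adjusted p = 0.416). MHC class II presentation fell for 9 of 12 (3 rose, median -0.56), with H2-Ob, which restrains peptide loading, at -2.35 ± 0.16 and the class II transactivator gene Ciita at -1.86 ± 0.20, while the lysosomal protease gene Lgmn rose (2.81 ± 0.20). Oxidative phosphorylation genes fell for 19 of 24 (median -0.54, adjusted p = 0.00292 and 0.656) and proliferation genes for 19 of 33 (2 rose, median -0.54). Ribosomal proteins fell for 13 of 17 (15 fell adjusted over the list alone, median -0.25, adjusted p = 0.00159 and 0.488). Chemokine receptor genes split, with Ccr7, which guides migration to lymph nodes, rising (1.96 ± 0.20) and Ccr2 falling (-2.09 ± 0.30). Of that list 6 of 11 fell and 3 rose (3 rose and 7 fell adjusted over the list alone, median -0.91, adjusted p = 0.352). In the prostaglandin and leukotriene pathway 9 of 16 fell and 2 rose (median -0.58, adjusted p = 0.197), and Ptger4, which encodes prostaglandin E2 receptor EP4, rose (2.06 ± 0.19). Glycolysis (9 of 16 fell and 4 rose, median -0.45, adjusted p = 0.402) and the unfolded protein response (7 of 16 fell and 4 rose, 4 rose and 8 fell adjusted over the list alone, median -0.24, adjusted p = 0.916) had no set shift that passed. Nor did the set test pass for tolerance-associated DC genes (7 of 15 rose and 5 fell, median 0.43, adjusted p = 0.245) or immediate-early and tissue-digestion stress genes (6 of 23 rose and 5 fell, median -0.11, adjusted p = 0.549). The same held for TLR and nucleic acid sensing (11 of 24 fell and 5 rose, median -0.41, adjusted p = 0.679). Tlr9 rose by 1.02 ± 0.11. In all 6475 genes were called, 2370 higher and 4105 lower, of which 818 and 1141 changed at least 2-fold. Centring each array on its own median moved the median of all genes by 0.246 and turned the split into 4033 higher and 2778 lower. The median of the ribosomal proteins was then -0.005, which ended that call. Set tests of the chemokine, cytokine, MHC class II and proliferation lists passed narrowly in this comparison, at camera adjusted p values from 0.032 to 0.0476, and not after quantile normalization, so no list shift is given for them.

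In CD8+ cDC of NOD mice Ifit3 rose by 6.10 ± 0.25, Ifit1 by 5.33 ± 0.23, the nucleotidyltransferase-like gene Oasl2 by 4.83 ± 0.16, Rsad2 by 4.74 ± 0.25 and Sct by 5.49 ± 0.25. Of the type I IFN-stimulated genes 42 of 44 rose (median 2.81, adjusted p = 3.92e-56 and 0.0259), and of the IFN-inducible GTPases 9 of 11 rose and 1 fell (median 1.68, adjusted p = 1.49e-07 and 0.0878), where Gbp3 did not pass (0.12). Ifi202b, an interferon-inducible DNA-binding gene at which inbred strains differ, rose by 4.53 ± 0.23 in NOD cells, against 0.07 in B6 cells, which did not pass. DC maturation genes rose for 17 of 22 (median 1.48, adjusted p = 6.83e-13 and 0.114), with the OX40 gene Tnfrsf4 at 2.09 ± 0.19 and Ccr7 at 2.01 ± 0.20. NF-kB targets rose for 16 of 25 (2 fell, median 0.72, adjusted p = 5.55e-07 and 0.114) and peptide loading for MHC class I for 11 of 15 (median 0.58, adjusted p = 3.08e-06 and 0.0878). Cytokine genes rose for 6 of 12 (3 fell, 7 rose and 3 fell adjusted over the list alone, median 0.71, adjusted p = 0.0043 and 0.114), with Il6 at 3.01 ± 0.21 and Il27 at 2.61 ± 0.18. The cDC1 markers fell for 17 of 22 (1 rose, median -0.95, adjusted p = 5.99e-05 and 0.408), Hepacam2 by most (-3.77 ± 0.17), and Itgax fell with a change of -1.12 ± 0.18. Further down were the C-type lectin gene Clec4b2 (-3.41 ± 0.17), the lysozyme gene Lyz2 (-2.71 ± 0.28) and the DC-SIGN family gene Cd209a (-2.52 ± 0.37). Oxidative phosphorylation genes fell for 10 of 24 (1 rose, median -0.28) and ribosomal proteins for 10 of 17 (11 fell adjusted over the list alone, median -0.17, adjusted p = 0.00694 and 0.632). For proliferation 1 of 33 rose (none adjusted over the list alone, median -0.04, adjusted p = 0.61). Il1b fell (-1.91 ± 0.24) and Ptger4 rose (1.83 ± 0.19). After median centring the median of the ribosomal proteins was -0.03 and did not pass. The set test of oxidative phosphorylation is not given, since its median was -0.08 without replicate 1 of CpG-treated NOD, and the test did not pass without it or without replicate 2 or 3 of NOD PBS (-0.244 and -0.226). The fit called 4567 genes, 1700 higher and 2867 lower, and 510 and 343 of these changed at least 2-fold. Median centring moved the median of all genes by 0.146 and gave 2370 higher and 1910 lower, and a fit of the 6 arrays compared alone called 2584 genes. B6 and NOD CD8+ cDC shared 1500 genes that rose and 2546 that fell, where independence would give 358.8 and 1048.2, and the changes correlated with r = 0.90 across genes, which are not independent replicates.

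In the CD11b+ cDC sort of B6 mice granzyme B, Gzmb, rose more than any other gene (6.50 ± 0.29), followed by Slfn4 (6.21 ± 0.25), AA467197 (6.05 ± 0.28), Cxcl10 (4.82 ± 0.28), Il6 (4.80 ± 0.21) and the interleukin-2 receptor gene Il2ra (4.78 ± 0.23). The type I IFN-stimulated genes rose for 44 of 44 (median 2.24, adjusted p = 1.57e-48 and 0.0183), Rsad2 (4.82 ± 0.25) and Mx2 (4.26 ± 0.23) foremost. Of the IFN-inducible GTPases 10 of 11 rose and 1 fell (median 2.39, adjusted p = 1.18e-11 and 0.0183). DC maturation genes rose for 19 of 22 (median 1.33, adjusted p = 6.61e-16 and 0.0329), including Il12b, which encodes the p40 chain of interleukin-12 (4.18 ± 0.17), Il15 (3.25 ± 0.20) and its receptor gene Il15ra (2.90 ± 0.23). NF-kB targets rose for 18 of 25 (20 rose adjusted over the list alone, median 0.82, adjusted p = 8.54e-09 and 0.037) and chemokines for 13 of 17 (2 fell, median 0.93, adjusted p = 6.47e-06 and 0.0329). Cytokines rose for 8 of 12 (3 fell, median 1.54, adjusted p = 0.000135 and 0.0329). Increases were also found for MHC class I peptide loading in 12 of 15 (median 1.01, adjusted p = 2.67e-11 and 0.0175) and apoptosis genes in 10 of 16 (1 fell, 11 rose and 2 fell adjusted over the list alone, median 0.69, adjusted p = 8.01e-06 and 0.0329). NK cell markers rose with them, as 11 of 12 rose and 1 fell (median 3.22, adjusted p = 6.09e-12 and 0.0329). Nkg7 was at 4.10 ± 0.29, perforin, Prf1, at 3.94 ± 0.22 and granzyme A, Gzma, at 3.71 ± 0.36. Xcl1, a chemokine gene of lymphocytes, rose as well (3.19 ± 0.28). T cell markers had no set shift that passed (2 of 6 rose and 1 fell, median 0.31, adjusted p = 0.355). The cDC2 markers fell for 10 of 18 (1 rose, 1 rose and 11 fell adjusted over the list alone, median -0.77, adjusted p = 0.000192 and 0.143), from Cd209a (-4.98 ± 0.37) to Itgam (-1.99 ± 0.24). Clec4a4 fell too (-1.71 ± 0.22). MHC class II presentation fell for 9 of 12 (3 rose, median -0.47, adjusted p = 0.0121 and 0.353). Cholesterol synthesis fell for 10 of 15 (1 rose, 1 rose and 11 fell adjusted over the list alone, median -0.54, adjusted p = 0.00259 and 0.271) and ribosomal proteins for 15 of 17 (median -0.27, adjusted p = 3.39e-06 and 0.22). The prostaglandin-degrading enzyme gene Hpgd (-2.87 ± 0.22) and the macrophage elastase gene Mmp12 (-3.49 ± 0.20) were among the genes that fell most, and Ptger4 (1.34 ± 0.19) and the transcriptional repressor gene Zbtb32 (1.35 ± 0.26) rose. Of the candidate genes in NOD diabetes susceptibility regions 6 of 10 rose and 2 fell (median 0.48, adjusted p = 0.0147 and 0.037), among them the 4-1BB gene Tnfrsf9 (2.35 ± 0.12) and Cd101 (-1.89 ± 0.15). Red pulp macrophage markers had no set shift that passed (4 of 10 fell and 1 rose, median -0.39, adjusted p = 0.301). Too few monocyte (2 of 4 fell and 1 rose), erythroid (1 of 3 rose), platelet (1 of 4 fell, none adjusted over the list alone) and stroma and endothelium markers (1 of 3 rose) were measured for the set test. In total 4364 genes were called, 1782 higher and 2582 lower, with 628 and 424 changed at least 2-fold, and median centring, which moved the median of all genes by 0.122, gave 2309 and 1909.

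CD11b+ cDC of NOD mice raised Cxcl10 (5.08 ± 0.28), Rsad2 (4.85 ± 0.25), Slfn1 (4.70 ± 0.21), Slfn4 (4.43 ± 0.25) and 2 genes of the interferon-inducible Ifi200 family, Ifi206 (4.41 ± 0.29) and Ifi202b (4.32 ± 0.23). All measured type I IFN-stimulated genes rose, as 44 of 44 rose (median 2.55, adjusted p = 4.99e-89 and 0.00243), and of the IFN-inducible GTPases 10 of 11 rose (median 2.25, adjusted p = 1.62e-18 and 0.00243). Cytokine genes rose for 8 of 12 (8 rose and 1 fell adjusted over the list alone, median 1.30, adjusted p = 7.82e-09 and 0.00243), including Il12b (3.59 ± 0.17), Il6 (3.42 ± 0.21) and Il15 (3.37 ± 0.20). Chemokines rose for 9 of 17 (2 fell, 11 rose and 2 fell adjusted over the list alone, median 0.99, adjusted p = 3.78e-07 and 0.0157) and DC maturation genes for 16 of 22 (median 1.07, adjusted p = 2.42e-17 and 0.031). NF-kB targets rose for 14 of 25 (17 rose adjusted over the list alone, median 0.56, adjusted p = 1.55e-08 and 0.0449). Of the MHC class I peptide loading genes 11 of 15 rose and 1 fell (median 0.82, adjusted p = 6.28e-12 and 0.00325), and of the apoptosis genes 8 of 16 rose (median 0.35, adjusted p = 5.2e-06 and 0.031). TLR and nucleic acid sensing genes rose for 8 of 24 (1 fell, 10 rose and 1 fell adjusted over the list alone, median 0.23, adjusted p = 0.000535 and 0.249), with Tlr3 at 1.11 ± 0.22 and Tlr9 at 1.08 ± 0.11. NK cell markers rose for 6 of 12 (7 rose and 1 fell adjusted over the list alone, median 0.72, adjusted p = 3.65e-05 and 0.21), with Gzmb at 3.42 ± 0.29 and Gzma at 3.32 ± 0.36. Of the cDC2 markers 6 of 18 fell and 3 rose (3 rose and 7 fell adjusted over the list alone, median -0.21, adjusted p = 0.113), with Cd209a at -3.90 ± 0.37 and Itgam at -1.41 ± 0.24. Clec4a4 did not pass (-0.13). MHC class II presentation (3 of 12 rose and 1 fell, median -0.03, mean 0.08, adjusted p = 0.725) and cholesterol synthesis (1 of 15 fell, none adjusted over the list alone, median -0.10, adjusted p = 0.211) had no set shift that passed. Ribosomal proteins fell for 9 of 17 (11 fell adjusted over the list alone, median -0.20, adjusted p = 1.25e-05 and 0.26). Cd101 fell (-1.86 ± 0.15), and Ptger4 rose (0.78 ± 0.19), a call that ended without replicate 1 of CpG-treated NOD CD11b+ cDC (0.64). The 1732 genes called were 1089 higher and 643 lower, with 351 and 57 changed at least 2-fold. Weighting the arrays by their spread raised the count to 2623, and leaving out replicate 1 of CpG-treated NOD CD11b+ cDC lowered it to 1139. The strains shared 936 genes that rose and 525 that fell in this subset, with 172.8 and 147.9 under independence and r = 0.80 across genes. Ifnb1, the gene of interferon beta, was too dim to be tested. Its means under PBS and CpG were 3.96 and 5.43 in B6 CD8+, 4.10 and 5.37 in NOD CD8+, 3.77 and 5.55 in B6 CD11b+ and 3.96 and 4.13 in NOD CD11b+ cDC.

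**Figure D2:**
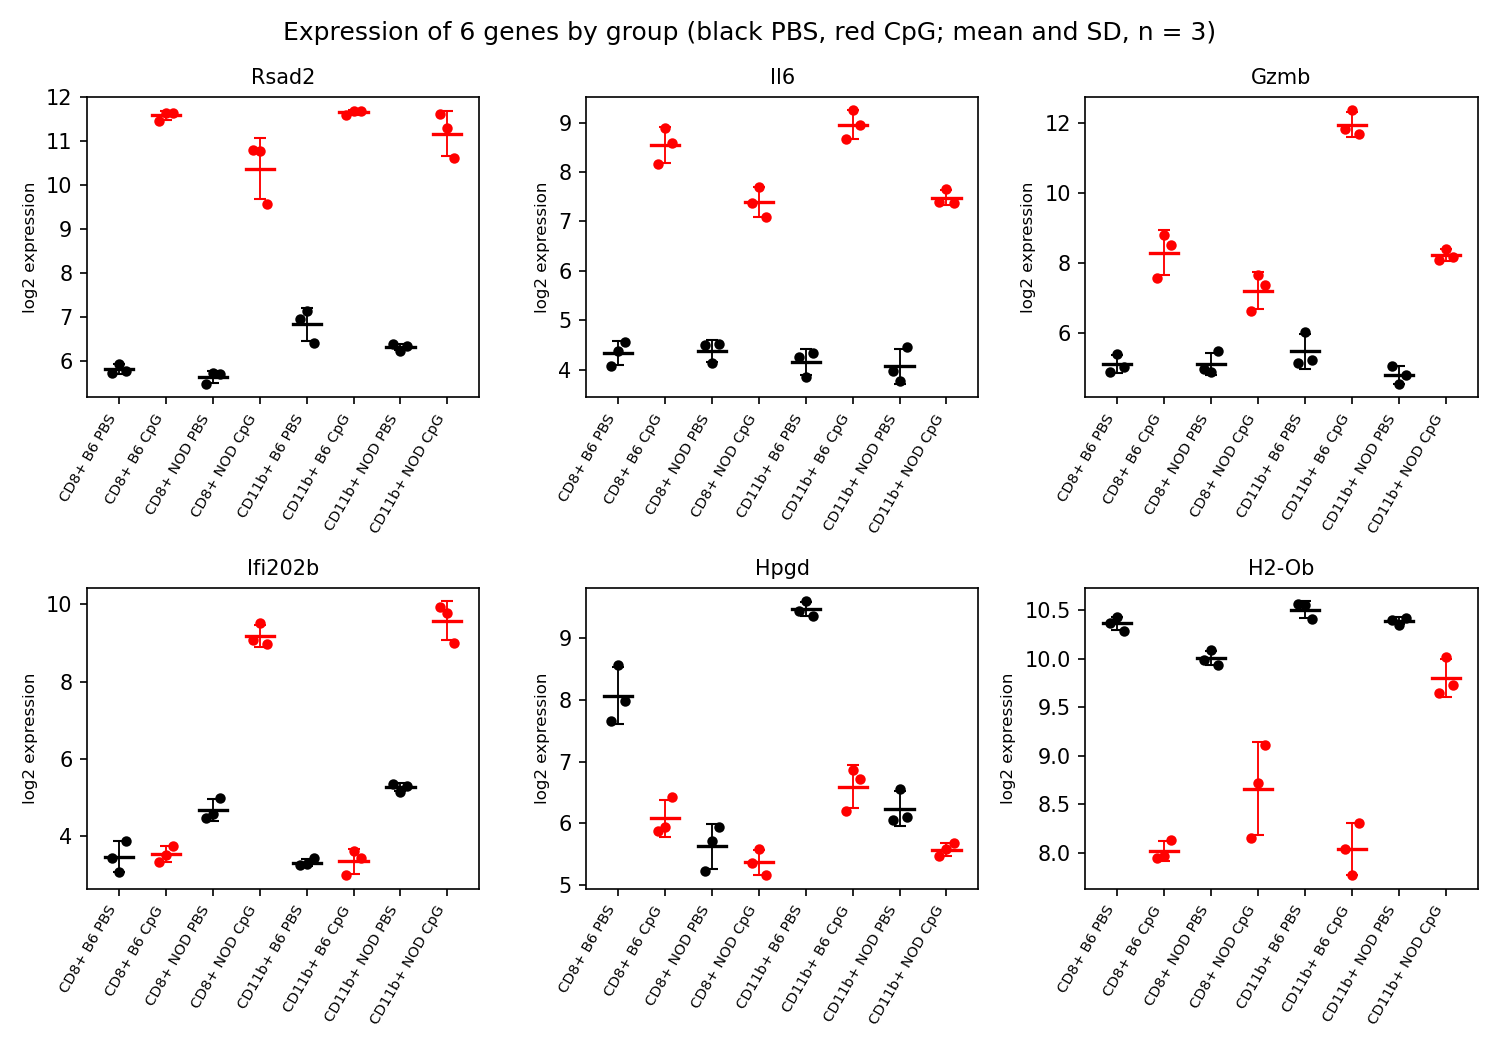
Log2 expression (y axis) of Rsad2, Il6, Gzmb, Ifi202b, Hpgd and H2-Ob on the 24 arrays in the 8 groups (x axis). Points are arrays, bars are group means and whiskers 1 standard deviation with n = 3, and black is PBS and red CpG. Rsad2 was higher with CpG in every group pair, by 5.76, 4.74, 4.82 and 4.85 in B6 CD8+, NOD CD8+, B6 CD11b+ and NOD CD11b+ cDC, whereas Ifi202b was higher with CpG in NOD mice alone.

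Whether the strains respond differently was tested as the interaction of strain with CpG, in which a positive value means a more positive change in NOD. In CD8+ cDC Ifi202b had the highest value (4.46 ± 0.32) and AA467197 (-4.38 ± 0.40), the cystatin gene Csta2 (-3.99 ± 0.31), the zinc finger gene Zfp872 (-3.42 ± 0.32) and Gbp3 (-3.11 ± 0.25) the lowest. The kinase gene Melk (1.91 ± 0.23), the inflammasome sensor gene Nlrp1b (1.83 ± 0.20), the inhibitory Fc receptor gene Fcgr2b (1.70 ± 0.32), Hpgd (1.72 ± 0.31) and Tgfbi (1.67 ± 0.25) were also more positive in NOD. Nlrp1b was lower in NOD CD8+ cDC already under PBS, which leaves less room for a fall with CpG. On the list of DC maturation and co-stimulation Cd200 (-1.54 ± 0.28), Tnfsf9, the 4-1BB ligand gene (-1.53 ± 0.24) and the CD27 ligand gene Cd70 (-1.28 ± 0.22) had negative values, and in all 4 of 22 were lower and 1 higher (1 higher and 7 lower adjusted over the list alone, median -0.38, adjusted p = 8.32e-05 and 0.732). The interleukin-1 receptor antagonist gene Il1rn (-1.62 ± 0.26) was less induced in NOD cells, as was Il2ra (-2.11 ± 0.33). Of the type I IFN-stimulated genes 3 of 44 were lower (median -0.18, adjusted p = 0.000553 and 0.774), among them Trim25 (-1.15 ± 0.16). For MHC class II presentation 3 of 12 were higher (7 higher adjusted over the list alone, median 0.41, adjusted p = 0.000543 and 0.732). Of the cDC1 markers 2 of 22 were higher (8 higher adjusted over the list alone, median 0.64, adjusted p = 8.32e-05 and 0.732), and of the proliferation genes 1 of 33 were higher (none adjusted over the list alone, median 0.55, adjusted p = 5.11e-05 and 0.76). With camera the last 4 lists passed only at the preset correlation, and of these 4 the MHC class II list alone passed fry. Cd8a (0.22), Tlr9 (0.10) and Ptger4 (-0.23) did not pass. Without replicate 3 of CpG-treated NOD mice the median of the IFN-stimulated genes was -0.03 and its test did not pass, and that of the cDC1 markers was 0.38. The median of the IFN-stimulated genes was -0.31 without replicate 1 of that group. For DC maturation it was -0.25 without replicate 3 of B6 PBS and -0.23 without replicate 1 of NOD PBS. The fit called 451 genes, 195 higher and 256 lower. Leaving out replicate 1 of CpG-treated NOD mice raised the count to 2071. It fell to 257 without replicate 3 of the same group, 277 without replicate 1 of NOD PBS, 231 without replicate 2 of B6 CpG and 255 without replicate 3 of B6 PBS. It was 2533 with array weights and 164 in a fit of the 12 arrays of this subset alone.

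In CD11b+ cDC the interaction of strain with CpG had extreme values at genes also named for CD8+ cDC, Ifi202b (4.29 ± 0.32) and Melk (2.82 ± 0.23) above and Csta2 (-4.33 ± 0.31), AA467197 (-3.91 ± 0.40) and Zfp872 (-3.63 ± 0.32) below. Negative values were also found for Gzmb (-3.08 ± 0.41), Prf1 (-3.08 ± 0.32), the NK receptor gene Klrb1c (-3.31 ± 0.40), interferon gamma, Ifng (-3.37 ± 0.32), the Fas ligand gene Fasl (-2.89 ± 0.29) and Thy1 (-3.01 ± 0.35). Of the NK cell markers 8 of 12 were lower (10 lower adjusted over the list alone, median -1.82, adjusted p = 1.95e-16 and 0.0642). Of the MHC class II genes 7 of 12 were higher (8 higher adjusted over the list alone, median 0.44, adjusted p = 3.25e-07 and 0.203), with H2-Ob at 1.88 ± 0.23, H2-Oa at 1.24 ± 0.20 and H2-DMa at 1.07 ± 0.22. With the estimated correlation neither list passed. Of the cDC2 markers 3 of 18 were higher (4 higher adjusted over the list alone, median 0.55, adjusted p = 2.69e-05 and 0.231), among them Clec4a2 (1.63 ± 0.24) and Clec4a4 (1.58 ± 0.31). Il6 (-1.39 ± 0.30), Cd86 (-1.12 ± 0.18), Cd200 (-1.43 ± 0.28) and Tnfrsf9 (-1.94 ± 0.18) were less induced, and 2 of 22 were lower among DC maturation genes (median -0.33, adjusted p = 7.87e-05 and 0.419). Of the type I IFN-stimulated genes 3 of 44 were higher and 1 lower (5 higher and 1 lower adjusted over the list alone, median 0.22), with Oasl2 at 1.02 ± 0.22. Hpgd (2.21 ± 0.31) led the prostaglandin and leukotriene pathway (3 of 16 were higher, 5 higher and 1 lower adjusted over the list alone, median 0.36). Of the cholesterol synthesis genes 3 of 15 were higher (5 higher adjusted over the list alone, median 0.35, adjusted p = 0.00221 and 0.397), and of the red pulp macrophage markers 1 of 10 were higher (4 higher adjusted over the list alone, median 1.11, adjusted p = 0.00135 and 0.451). The median of the type I IFN-stimulated genes was 0.12 without replicate 1 and 0.38 without replicate 3 of NOD CpG, and that of DC maturation -0.20 without the latter. The fit called 492 genes, 270 higher and 222 lower, and median centring, which moved the median of all genes by -0.105, gave 219 higher and 293 lower. The count was 297 without replicate 2 of CpG-treated NOD, 314 without replicate 1 of B6 CpG and 316 without replicate 1 of B6 PBS, and it was 1239 with array weights and 945 in a fit of this subset alone.

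The strains were next compared without CpG. In PBS-treated CD8+ cDC the antiviral family gene Trim12a (-4.25 ± 0.18), the apolipoprotein L gene Apol7c (-3.69 ± 0.28), the protease inhibitor gene Spint1 (-3.08 ± 0.18) and apolipoprotein E, Apoe (-2.89 ± 0.18), were lower in NOD than in B6. So were the histone genes H2bc4 (-2.92 ± 0.40) and H2bc8 (-2.72 ± 0.21). Cmah, which makes the sialic acid Neu5Gc (2.98 ± 0.28), langerin, Cd207 (2.75 ± 0.24), Gbp3 (2.66 ± 0.17), and the transcript BC018473 (2.62 ± 0.22) were higher. Of the B cell markers 6 of 13 were higher (12 higher adjusted over the list alone, median 1.18, adjusted p = 1.59e-10 and 0.357). Among them were the immunoglobulin gene Ighm at 2.41 ± 0.46 and the complement receptor gene Cr2 at 2.18 ± 0.45, and the variable gene Igkv5-43 moved with them (3.12 ± 0.57). Of the cholesterol synthesis genes 5 of 15 were lower (9 lower adjusted over the list alone, median -0.38, adjusted p = 7.96e-11 and 0.117), with Idi1 at -1.47 ± 0.14. Of the type I IFN-stimulated genes 5 of 44 were lower (7 lower adjusted over the list alone, median -0.17, adjusted p = 7.18e-07 and 0.54). Of the plasma cell markers 1 of 4 were higher (2 higher adjusted over the list alone, median 0.76), and of the pDC markers 1 of 9 were higher (3 higher adjusted over the list alone, median 0.35, adjusted p = 0.00113 and 0.435). Red pulp macrophage markers had 6 of 10 lower adjusted over the list alone (median -1.10, adjusted p = 0.000362 and 0.519). That call ended without replicate 2 of B6 PBS, at -0.58. MHC class II presentation was lower for 2 of 12 (median -0.08), with H2-Ab1 at -0.44 ± 0.07. Il12b was lower (-2.39 ± 0.17), as was Icos, in a diabetes susceptibility region (-1.26 ± 0.14). Tlr9 (-0.09), Il1b (-0.01), Ptger4 (-0.29), Itgax (-0.21) and Zbtb32 (0.06) did not pass. The median of the type I IFN-stimulated genes was -0.09 without replicate 2 of NOD PBS. That of MHC class II was -0.15 without replicate 1, and without replicate 3 its set test did not pass (-0.066). The fit called 407 genes, 228 higher and 179 lower, and leaving out replicate 3 of B6 PBS gave 271. Median centring gave 226 higher and 230 lower. Array weights gave 714.

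In PBS-treated CD11b+ cDC Apol7c (-5.92 ± 0.28), Trim12a (-4.69 ± 0.18), Spint1 (-3.36 ± 0.18), Hpgd (-3.23 ± 0.22) and H2bc8 (-3.24 ± 0.21) were again lower in NOD. BC018473 (5.06 ± 0.22), cytoglobin, Cygb (3.83 ± 0.17), the sialyltransferase gene St6galnac2 (3.61 ± 0.19), the Ly49 family gene Klra17 (3.18 ± 0.26) and Cmah (3.08 ± 0.28) were higher. Interferon-stimulated genes were lower in unstimulated NOD cells, as 19 of 44 were lower (25 lower adjusted over the list alone, median -0.44, adjusted p = 1.94e-20 and 0.272). They included Oasl2 (-1.15 ± 0.16), Ifi27l2a (-1.14 ± 0.23) and the regulator gene Irf7 (-1.01 ± 0.14). Chemokines were lower for 5 of 17 (7 lower adjusted over the list alone, median -0.44, adjusted p = 5.36e-06 and 0.145), with Xcl1 at -1.67 ± 0.28 and Cxcl16 at -0.72 ± 0.15. In DC maturation 4 of 22 were lower and 1 higher (1 higher and 8 lower adjusted over the list alone, median -0.31, adjusted p = 0.000786 and 0.621), with Il15 lower (-1.48 ± 0.20) and Cd86 higher (0.69 ± 0.13). Proliferation genes were lower for 4 of 33 (median -0.40, adjusted p = 9.42e-09 and 0.464), with Bub1b at -1.57 ± 0.18. Red pulp macrophage markers were lower, as 6 of 10 were lower (9 lower adjusted over the list alone, median -1.27, adjusted p = 1.53e-07 and 0.272). Of the NK cell markers 4 of 12 were lower (6 lower adjusted over the list alone, median -0.69, adjusted p = 2.51e-06 and 0.272). Members that were higher were found among B cell (2 of 13 were higher, median 0.59, adjusted p = 0.000192 and 0.621), neutrophil (3 of 5 were higher and 1 lower, median 0.80) and plasma cell markers (3 of 4 were higher, median 1.03). Ighm was at 2.42 ± 0.46 and Jchain at 2.73 ± 0.41. Cd8a, which is low in this subset, was lower still in NOD (-1.52 ± 0.26), and Itgam (-0.22), Tlr9 (0.00) and Il1b (-0.06) did not pass. Single arrays moved some list medians by over 1.5 times. Chemokines were at -0.25 without replicate 1 of NOD PBS, NK cell markers at -0.44 without replicate 2 of B6 PBS, and B cell markers at 0.89 and 0.24 without replicates 1 and 3 of NOD PBS. The fit called 628 genes, 271 higher and 357 lower, and array weights gave 1046. Both subsets shared 94 genes higher in NOD and 107 lower, against 5.5 and 5.7 under independence.

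After CpG the fit of all arrays called more genes between the strains than under PBS. In CD8+ cDC a fit of the 6 arrays compared alone turned this around, with 588 genes under PBS and 390 after CpG. Ifi202b in this subset was higher in NOD by 5.67 ± 0.23, and Zfp872 (-5.63 ± 0.23), Trim12a (-4.86 ± 0.18), AA467197 (-4.69 ± 0.28) and Csta2 (-3.88 ± 0.22) were lower. Interferon-stimulated genes were lower for 21 of 44 (24 lower adjusted over the list alone, median -0.44, adjusted p = 5.66e-12 and 0.566), with the ubiquitin ligase gene Trim25 at -1.27 ± 0.11 and the kinase gene Cmpk2 at -1.09 ± 0.25. DC maturation genes were lower for 8 of 22 (1 higher and 9 lower adjusted over the list alone, median -0.35, adjusted p = 1.07e-05 and 0.566), with Cd200 at -1.32 ± 0.20, Il12b at -1.32 ± 0.17 and Cd70 at -1.24 ± 0.16. Il6 (-1.15 ± 0.21) and Il15 (-0.94 ± 0.20) were lower as well. The cDC1 markers were higher for 9 of 22 (11 higher and 1 lower adjusted over the list alone, median 0.46, adjusted p = 0.00276 and 0.566), with Itgae at 1.66 ± 0.26. Of the B cell markers 5 of 13 were higher (6 higher adjusted over the list alone, median 1.02), and of the plasma cell markers 2 of 4 were higher (median 0.63). Cholesterol synthesis was lower for 4 of 15 (1 higher, 1 higher and 6 lower adjusted over the list alone, median -0.13). The fit called 2270 genes, 1390 higher and 880 lower, of which 136 and 139 differed at least 2-fold. Median centring moved the median of all genes by -0.123 and gave 936 higher and 1452 lower. List medians rested on single arrays of NOD CpG. Without replicate 3 they were -0.26 for IFN-stimulated genes, -0.23 for DC maturation and 0.28 for cDC1 markers, the last at 0.73 without replicate 1. B cell markers were at 0.60 without replicate 2, and their set test then did not pass. The count rested on single arrays too. It was 3945 without replicate 1 and 1111 without replicate 3 of NOD CpG, 1468 without replicate 1 and 1452 without replicate 2 of B6 CpG. With array weights, by which replicate 2 of NOD CpG dominates its group, it was 5089.

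In CpG-treated CD11b+ cDC Ifi202b (6.24 ± 0.23), BC018473 (4.88 ± 0.22), Klra17 (4.05 ± 0.26), Cygb (3.77 ± 0.17) and Mmp12 (3.29 ± 0.20) were higher in NOD. Apol7c (-6.77 ± 0.28), Trim12a (-4.98 ± 0.18), the NK receptor gene Klrc1 (-4.81 ± 0.41), Ncr1 (-4.32 ± 0.27) and Il2rb (-3.79 ± 0.32) were lower. NK cell markers were lower for 10 of 12 (11 lower adjusted over the list alone, median -3.34, adjusted p = 8.13e-17 and 0.0587). DC maturation genes were lower for 13 of 22 (median -0.40, adjusted p = 8.22e-09 and 0.259), with Cd200 at -1.85 ± 0.20, Ccl22, which attracts regulatory T cells, at -1.72 ± 0.19 and Il15 at -1.36 ± 0.20. Lower too were chemokines (6 of 17 were lower, median -0.26, adjusted p = 0.001 and 0.259) and NF-kB targets (7 of 25 were lower and 1 higher, 1 higher and 11 lower adjusted over the list alone, median -0.28, adjusted p = 0.000293 and 0.286). The same direction was found for MHC class I peptide loading (6 of 15 were lower, median -0.23, adjusted p = 0.001 and 0.259) and apoptosis genes (8 of 16 were lower, median -0.39, adjusted p = 0.000557 and 0.259). Interferon-stimulated genes were lower for 8 of 44 (4 lower adjusted over the list alone, median -0.19, adjusted p = 7.69e-05 and 0.591), with Trim25 at -0.91 ± 0.11 and Oasl1 at -0.84 ± 0.20. MHC class II presentation was higher for 7 of 12 (median 0.28, adjusted p = 0.000557 and 0.286), with H2-Ob at 1.76 ± 0.16 and Ciita at 1.01 ± 0.20. B cells express these genes too, and of the B cell markers 5 of 13 were higher (median 0.87, adjusted p = 0.00294 and 0.591), with a median of 0.46 without replicate 3 of NOD CpG. Of the plasma cell markers 2 of 4 were higher and 1 lower (3 higher and 1 lower adjusted over the list alone, median 1.02). Also higher were cDC2 markers for 8 of 18 (10 higher adjusted over the list alone, median 0.45, adjusted p = 0.000557 and 0.286), and Clec4a4 by 1.71 ± 0.22. Among IL-1 family genes the decoy receptor gene Il1r2 was higher (2.15 ± 0.27) and Il1rn lower (-1.74 ± 0.18), and the list had no set shift that passed (5 of 22 were higher and 4 lower, median 0.03, adjusted p = 0.979). Ptger4 (-1.10 ± 0.19) and Tnfrsf9 (-2.21 ± 0.12) were lower. Without replicate 3 of NOD CpG the chemokine median was -0.14 and that of the IFN-stimulated genes -0.10, the latter at -0.30 without replicate 1. The fit called 2600 genes, 1565 higher and 1035 lower, of which 273 and 242 differed at least 2-fold, and median centring gave 1259 and 1412.

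**Figure D3:**
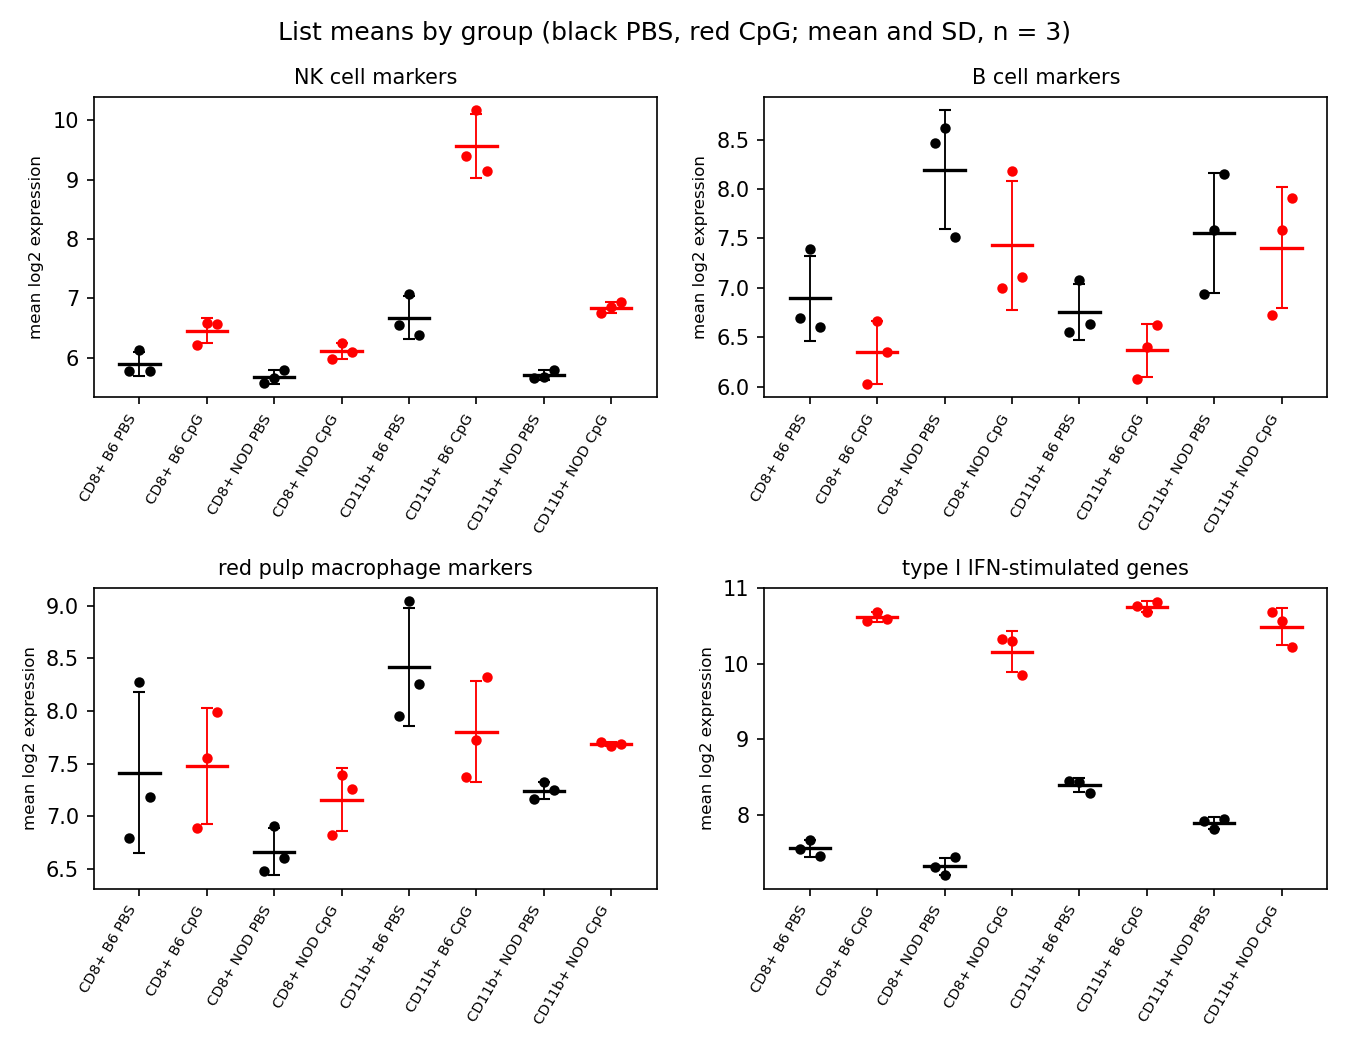
Mean log2 expression (y axis) over 4 marker or response lists on each of the 24 arrays, by group (x axis). Points are arrays, bars are group means and whiskers 1 standard deviation with n = 3, and black is PBS and red CpG. The NK cell marker mean was highest in B6 CD11b+ cDC with CpG, at 9.57 against 6.67 with PBS. Under PBS the B cell marker means of NOD and B6 groups were 8.2 and 6.9 in CD8+ and 7.56 and 6.76 in CD11b+ cDC.

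Whether the subsets respond differently to CpG was tested in each strain, a positive value meaning a more positive change in CD8+ cDC. In B6 mice Rtp4 (3.21 ± 0.34), Ifit3 (2.83 ± 0.35) and the signalling gene Stat4 (2.42 ± 0.38) had more positive changes in CD8+ cDC. Il12b (-3.71 ± 0.24), Gzmb (-3.31 ± 0.41), Irf8, a transcription factor gene of CD8+ cDC (-1.95 ± 0.20), and Il1b (-1.83 ± 0.35) had more negative ones. Of the type I IFN-stimulated genes 18 of 44 were higher (21 higher and 1 lower adjusted over the list alone, median 0.44, adjusted p = 1.23e-10 and 0.361). Of the cDC1 markers 12 of 22 were lower (1 higher and 16 lower adjusted over the list alone, median -1.23, adjusted p = 1.29e-09 and 0.361), and of the NK cell markers 12 of 12 were lower (median -2.58, adjusted p = 2.16e-13 and 0.137). In NOD mice Stat4 (2.85 ± 0.38), the interleukin-23 receptor gene Il23r (2.72 ± 0.31), Ifit3 (2.33 ± 0.35) and Rtp4 (2.22 ± 0.34) were more positive. Il12b (-2.04 ± 0.24), Cxcl9 (-2.04 ± 0.22), Tlr3 (-2.05 ± 0.31) and Il1b (-1.84 ± 0.35) were more negative. Of the chemokines 8 of 17 were lower (median -0.60, adjusted p = 0.000304 and 0.36), and of the cDC1 markers 8 of 22 were lower (11 lower adjusted over the list alone, median -0.77, adjusted p = 1.19e-07 and 0.435). For NK cell markers 2 of 12 were lower (3 lower adjusted over the list alone, median -0.53). Itgam was more positive in CD8+ cDC of B6 mice (1.84 ± 0.34). The counts were 1502 genes in B6 (656 higher and 846 lower) and 764 in NOD (301 and 463). Median centring, which moved the median of all genes by 0.123 and 0.129, gave 979 and 719 in B6 and 441 and 348 in NOD. Array weights gave 2409 and 2321. The NOD count ran from 479 to 1676 when single arrays were left out, with 479 without replicate 3 of CD8+ PBS, 485 without replicate 1 and 1676 without replicate 3 of CD8+ CpG, and 482 without replicate 2 of CD11b+ CpG. It was 303 in a fit of the NOD arrays alone.

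Strain differences under PBS that differed between subsets numbered 99, with 50 more positive in CD8+ cDC and 49 more negative. Gzma (2.84 ± 0.51), Apol7c (2.23 ± 0.39), Cd207 (2.56 ± 0.34) and Gbp3 (2.00 ± 0.25) were more positive, and BC018473 (-2.43 ± 0.31), Cygb (-2.28 ± 0.24) and the receptor gene Trem1 (-2.44 ± 0.32) more negative. Chemokines as a list were more positive, as 3 of 17 were higher (8 higher adjusted over the list alone, median 0.58, adjusted p = 3.66e-08 and 0.0282). The 3-way test of whether the strain difference in the CpG response differs between subsets called 35 genes, 19 higher and 16 lower. Klrb1c (3.47 ± 0.56), Ifng (3.14 ± 0.45), Prf1 (2.61 ± 0.45) and Thy1 (3.05 ± 0.50) were above 0 and Gbp3 (-1.98 ± 0.35) below 0, and among NK cell markers 2 of 12 were higher (8 higher adjusted over the list alone, median 1.64, adjusted p = 1.13e-14 and 0.0988). The first count was 63 without replicate 3 of B6 CD8+ PBS or replicate 2 of NOD CD11b+ PBS and ran from 51 with a stricter filter to 195 with array weights. The second ran from 10 with a stricter filter to 233 with array weights. It was 19 to 23 without replicate 1 or 3 of B6 CD8+ PBS, 2 of B6 CD8+ CpG, 1 of NOD CD8+ PBS, 1 or 3 of B6 CD11b+ PBS, 1 of B6 CD11b+ CpG, 3 of NOD CD11b+ PBS or 2 of NOD CD11b+ CpG. It was 70 without replicate 1 of NOD CD8+ CpG and 55 without replicate 3 of B6 CD11b+ CpG. Of the 185 set shifts that passed with camera over all comparisons, 28 passed with an estimated correlation. These were the type I IFN-stimulated genes after CpG in NOD CD8+ cDC. In CD11b+ cDC of both strains after CpG they were the type I IFN-stimulated genes, IFN-inducible GTPases, NF-kB targets, DC maturation, MHC class I peptide loading, chemokines, cytokines and apoptosis genes. In B6 they also included the candidate susceptibility genes and NK cell markers, and in NOD the tolerance-associated DC genes (6 of 15 rose, 7 rose adjusted over the list alone, median 0.34, adjusted p = 0.0132 and 0.0382). The rest were the cDC1, cDC2 and MHC class I peptide loading lists between subsets in both strains, neutrophil markers between subsets in NOD, and chemokines in the test of subset by strain.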

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

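The tests of explanations, the exchanges of array labels and the reassignments of residuals in this part were chosen after the results they concern had been seen, while the interaction tests were planned. Every result in this paragraph and the next is given because an interaction test found a response that differs between strains or subsets. The interaction of strain with CpG called 451 genes in CD8+ and 492 in CD11b+ cDC, that of subset with CpG 1502 in B6 and 764 in NOD, that of subset with strain under PBS 99, and the 3-way test 35. Among 100 splits with labels exchanged between groups within each level of the other factor, the real one included, 11, 7, 7, 8, 9 and 6 called as many genes, so chance was not excluded by this test. The highest other counts were 1722, 2516, 2560, 2743, 988 and 1626. Except for subset by CpG in B6 these counts are several times the real ones, and point to a structure of the samples. Part of it may be the main effects. A split that keeps most labels at 1 level and exchanges most at another can turn a main effect into an interaction. Of the other splits that called as many, 5 of 10, 3 of 6, 6 of 6, 5 of 7, 8 of 8 and 5 of 5 were of this kind. Of all 99 other splits 47, 51, 48, 41, 54 and 84 were. For strain by CpG in both subsets and the 3-way test the first shares are thus near those among all splits. Without such splits the highest counts were 989, 640, 839, 920, 65 and 19, which exceed the real count for strain by CpG in both subsets and for subset by CpG in NOD. Splits that exchange labels less unequally stay among these and can carry part of a main effect. These counts therefore do not tell a main effect from another structure. A reassignment of residuals was added after these first counts had been seen. With the residuals of the fit without the interaction reassigned among the arrays, 4, 1, 1, 1, 1 and 1 of 100 assignments called as many, the real one included. These shares lie under 0.05, for strain by CpG in CD8+ cDC by a narrow margin. The highest other counts there were 1253, 38, 63, 77, 12 and 14. That reassignment ignores that same-numbered arrays deviate together. With residuals reassigned only among arrays of the same number, a test added later still, 2, 1, 3, 2, 2 and 1 of 100 called as many. These shares lie under 0.05 too, with highest other counts of 509, 41, 1792, 930, 118 and 0. Since the tests were added in turn and differ in outcome from the exchange of labels, chance is not called excluded for these counts.

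By gene, the strain by CpG values in CD8+ cDC were 4.46 for Ifi202b, 1.91 for Melk and 1.84 for Spint1 above 0 and -4.38 for AA467197, -3.99 for Csta2 and -3.42 for Zfp872 below 0. In CD11b+ cDC they were 4.29 for Ifi202b, 2.82 for Melk, 2.38 for Inpp4b and 1.58 for Clec4a4, and -4.33 for Csta2, -3.91 for AA467197 and -3.63 for Zfp872. Itgax was at 0.92 and 0.96, calls that ended in 10 of 12 fits with an array left out in each subset, at values from 0.62 to 1.17 and 0.91 to 1.01, and held only without replicate 1 of NOD CpG or replicate 3 of B6 CpG. In CD8+ cDC the list medians for strain by CpG that passed camera with each array left out were -0.54 for IFN-inducible GTPases, -0.25 for NF-kB targets, -0.38 for DC maturation, 0.41 for MHC class II, 0.55 for proliferation and 0.64 for cDC1 markers. Single arrays moved some by over 1.5 times, NF-kB targets to -0.16 (without B6 CpG 2), DC maturation to -0.25 and -0.23 (without B6 PBS 3 or NOD PBS 1) and cDC1 markers to 0.38 (without NOD CpG 3). Calls that ended with single arrays left out were type I IFN-stimulated genes at -0.18 (without NOD CpG 3, -0.03), MHC class I loading at -0.16 (without B6 PBS 3, B6 CpG 1, NOD PBS 3, NOD CpG 1 or NOD CpG 3, -0.21 to -0.12), oxidative phosphorylation at 0.24 (without B6 CpG 1, NOD PBS 1, NOD CpG 2 or NOD CpG 3, 0.17 to 0.20) and ribosomal proteins at 0.09 (without B6 CpG 1 or NOD CpG 2, 0.07), the last also reversing under median centring. Without NOD CpG 1 the type I IFN-stimulated genes were at -0.31 and oxidative phosphorylation at 0.38. In CD11b+ cDC these medians were -0.23 for NF-kB targets, -0.33 for DC maturation, -0.17 for MHC class I loading, 0.44 for MHC class II, 0.35 for cholesterol synthesis, 0.55 for cDC2, -1.82 for NK cell and 1.11 for red pulp macrophage markers. Here single arrays moved NF-kB targets to -0.14 (without B6 PBS 3 or NOD PBS 2) and, without NOD CpG 3, NF-kB targets to -0.07 and DC maturation to -0.20. Type I IFN-stimulated genes at 0.22 (without B6 PBS 1 or 2, B6 CpG 2, NOD PBS 2, NOD CpG 1 or 2, 0.12 to 0.22), the prostaglandin pathway at 0.36 (without B6 PBS 2 or NOD PBS 3, 0.26 and 0.44), apoptosis at -0.09 (without NOD CpG 3, 0.02) and ribosomal proteins at 0.11 (without B6 PBS 2 or NOD PBS 1, 0.10 and 0.07) did not hold with each array left out. Without NOD CpG 3 the type I IFN-stimulated genes were at 0.38, and apoptosis was at -0.19 and -0.14 without NOD CpG 1 or 2. Under median centring the ribosomal protein median was 0.004. With an estimated correlation between genes the lowest adjusted p was 0.732 in CD8+ and 0.0642 in CD11b+ cDC, so with camera all of these list calls rest on the preset correlation. Of the 10 and 12 lists 2 and 6 passed fry.

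The subset by CpG medians in B6 that passed with each array left out were 0.44 for type I IFN-stimulated genes, -0.31 for MHC class I loading, -0.55 for chemokines, -0.41 for oxidative phosphorylation, 0.35 for cholesterol synthesis, -1.23 for cDC1, 0.56 for cDC2 and -2.58 for NK cell markers. Calls that ended were cytokines at -0.58 (without CD8+ CpG 1, -0.40) and red pulp macrophage markers at 0.50 (without CD8+ PBS 1 or 3, CD8+ CpG 3, CD11b+ PBS 2 or CD11b+ CpG 1, 0.15 to 0.40). The latter rose to 0.77 to 1.00 without CD8+ PBS 2, CD8+ CpG 1, CD11b+ PBS 1 or CD11b+ CpG 3. Under median centring the MHC class I call in B6 ended (-0.182, adjusted p = 0.0583). In NOD the medians were -0.60 for chemokines, -0.31 for TLR and sensing genes and -0.77 for cDC1 markers. Calls that ended without CD8+ CpG 3 were IFN-inducible GTPases at -0.63 (-0.46), cytokines at -0.41 (-0.48), cholesterol synthesis at 0.29 (0.25, and 0.22 without CD11b+ CpG 1) and NK cell markers at -0.53 (-0.61). Type I IFN-stimulated genes at 0.14 did not hold without CD8+ PBS 2, CD8+ CpG 1 or 2, or CD11b+ CpG 3 (-0.04 to 0.02), and were at 0.28 without CD8+ CpG 3 and 0.09 and 0.08 without CD11b+ PBS 1 or 3. Without CD8+ PBS 1 the IFN-inducible GTPases were at -0.41, and without CD11b+ CpG 3 cytokines were at -0.62 and interleukin-1 genes at -0.32. Interleukin-1 genes at -0.21 did not hold without CD8+ PBS 1 or 2, CD8+ CpG 3, CD11b+ PBS 3 or CD11b+ CpG 1 or 2 (-0.23 to -0.17), nor MHC class II at -0.16 without CD8+ PBS 1 or 2, CD8+ CpG 2, CD11b+ PBS 3 or CD11b+ CpG 1 or 2 (-0.17 to -0.13), nor neutrophil markers at 0.60 without CD8+ PBS 2, CD8+ CpG 3, CD11b+ PBS 2 or 3, or CD11b+ CpG 3 (0.45 to 0.64). With an estimated correlation the lowest adjusted p of these lists was 0.137 in B6 and 0.36 in NOD, so with camera these calls rest on the preset correlation too. Of the 10 and 11 lists 8 and 7 passed fry.

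For the comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. For CpG the real count and the highest of the other splits were 6475 and 1 in B6 CD8+, 4567 and 0 in NOD CD8+, 4364 and 0 in B6 CD11b+ and 1732 and 0 in NOD CD11b+ cDC. Between subsets they were 2442 and 2 in B6 and 2448 and 0 in NOD, and between strains 407 and 1 in CD8+ and 628 and 0 in CD11b+ cDC under PBS and 2600 and 0 in CD11b+ cDC after CpG. In CD8+ cDC after CpG 2 of the 10 splits called as many as the 2270 of the real one. The other, with 2678 genes, set B6 replicates 1 and 2 and NOD replicate 1 against the rest. It parts 1 of the 3 same-numbered pairs, which points to a structure of the samples. The splits that part all 3 pairs as the real one does called at most 1.

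NK cell markers were lower in NOD than in B6 CD11b+ cDC after CpG, with a median of -3.34 over all 12 and 10 called. Strain variants in Klr genes stay open for these. They are argued against for the 8 markers outside that family, also at -3.34 (-3.55 to -3.07 with single arrays left out). CpG-induced granule genes in the cDC themselves are argued against for the 8 receptors and transcription factors, with a median of -2.34 (-2.63 to -2). All 8 lay above the array median in CpG-treated B6 cells and 5 lay under it in NOD cells, so the size of this difference is uncertain. Induction in the cDC stays open for the 4 granule genes too, as they rose with CpG by medians of 3.12 in NOD CD11b+ and 1.24 in B6 CD8+ cDC. NK cells in the CD11b+ sort of B6 mice remain a candidate source, a hypothesis found and tested on the same data, and no gate against NK cells is stated besides the CD11c, CD8 and CD11b sort. The markers with the highest values, Gzmb, Nkg7 and Gzma, stood at 11.96, 11.95 and 11.56 in B6 against 8.22, 7.95 and 8.44 in NOD, levels of different probes that do not tell NK cells from induction in the cDC. Of the 12 markers 0 are on another list and 7 lay above the array median in PBS-treated B6 CD11b+ cDC, among them Klrd1 (10.69) and Klrk1 (7.96), which were not called lower (0.08 and -0.42). Why the strains would differ in such cells was not tested, and biology of the strains stays open.

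The CpG response was smaller in NOD than in B6, with noise-corrected slopes of NOD on B6 changes over all genes of 0.686 (jackknife SE 0.134) in CD8+ and 0.597 (0.057) in CD11b+ cDC. Regression dilution by noise in the B6 estimates is argued against by these slopes, which lie below 1 by more than 2 SE after the correction. A single shrinkage of all changes in NOD is argued against because type I IFN-stimulated genes had slopes of 0.936 (0.059) and 1.079 (0.067) and genes outside the IFN lists 0.668 (0.142) and 0.561 (0.056), which differ by 0.268 (0.107) and 0.518 (0.048). A single replicate number as the source is argued against by NOD to B6 ratios below 1 in 6 of 6 pairs of subset and number (0.87, 0.75 and 0.6 in CD8+, 0.67, 0.7 and 0.55 in CD11b+ cDC). The slopes and ratios include the NK cell markers, which were not removed. With CpG their mean went from 6.67 to 9.57 in B6 and from 5.71 to 6.84 in NOD CD11b+ cDC. How far such genes lower the slope in that subset is not known. A strain difference in the response, its timing at 12 h, the share of responding cells or other cells in the sort may underlie the pattern and was not tested.

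In all 4 comparisons of NOD with B6 the same 9 genes differed at least 4-fold in a fixed direction, Apol7c, D17H6S56E-5, H2bc8 and Trim12a lower and BC018473, Ighm, Igkv5-43, Klra17 and Zfp979 higher in NOD. NOD sequence variants under probes designed on the B6 genome would lower the signal. For the 4 lower genes they cannot be told apart from lower expression, since lower genes did not outnumber higher ones (exact one-sided binomial p = 0.746) and no probe-level values were used. For the 5 higher genes a variant that lowers the signal is argued against by their direction. Of these, Ighm and Igkv5-43 are immunoglobulin genes. B cell markers other than Ighm had medians of 1.17, 0.51, 0.97 and 0.85 between the strains in CD8+ PBS, CD11b+ PBS, CD8+ CpG and CD11b+ CpG. B cells in the sort of NOD mice are a candidate source of these 2 genes that cannot be told apart from strain biology, since the second median was 0.21 without replicate 3 of NOD CD11b+ PBS. Of the B cell markers in NOD CD8+ cDC under PBS, Cd79b stood at 9.76, Ighm at 9.46 and Cd79a at 9.24, and no gate against B cells is stated. Of the 13 B cell markers 0 are on another list, and 11 lay above the array median in PBS-treated B6 cells of each subset. Probes shared within the Klra, Apol and H2bc families and strain differences in gene content stay open and were not tested.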

How the results depend on the processing

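No alternative in this part was chosen after the data were seen, and the cause of a change was not tested except where an alternative itself tests fewer genes or uses fewer arrays. No filter, the mean of a gene's probe sets, every probe set, quantile normalization, median centring, eBayes without the trend and robust eBayes left each of the 16 counts within 1.5 times its value. Array weights let replicate 2 dominate the CpG-treated NOD CD8+ group. They gave 2623 genes for CpG in NOD CD11b+ cDC and 2533 and 1239 for strain by CpG in CD8+ and CD11b+ cDC. They gave 714, 1046 and 5089 for NOD against B6 in CD8+ PBS, CD11b+ PBS and CD8+ CpG, 2409 and 2321 for subset by CpG in B6 and NOD, 195 for subset by strain and 233 for the 3-way test. The fit of only the groups compared, which uses fewer arrays, gave 2584 for CpG in NOD CD8+ cDC, 164 and 945 for strain by CpG in CD8+ and CD11b+ cDC, 390 for NOD against B6 in CD8+ CpG. It gave 303 for subset by CpG in NOD and 181 for subset by strain. The stricter filter, which tests fewer genes, gave 51 for subset by strain and 10 for the 3-way test. A random block gave 1312 for subset by CpG in NOD, 153 for subset by strain and 75 for the 3-way test. With single arrays left out, so that a group of 2 is assumed to vary like the others, the counts ran from 1139 to 1836 for CpG in NOD CD11b+ cDC, 231 to 2071 and 297 to 524 for strain by CpG in CD8+ and CD11b+ cDC. For NOD against B6 they ran from 271 to 336 in CD8+ PBS and 1111 to 3945 in CD8+ CpG. They ran from 479 to 1676 for subset by CpG in NOD, 63 to 91 for subset by strain and 19 to 70 for the 3-way test and stayed within 1.5 times for the other 8 counts. The replicate number as a fixed block gave 728 and 766 for strain by CpG in CD8+ and CD11b+ cDC. Where same-numbered pairs were not all over 0.1, it gave 6687 for CpG in B6 CD8+ (pairs at 0.061 to 0.181), 4768 in B6 CD11b+ (-0.108 to 0.139). It gave 808 and 2931 for NOD against B6 in CD11b+ cDC under PBS (-0.1 to 0.192) and CpG (-0.003 to 0.187). For the interactions it gave 2009 and 1141 for subset by CpG, 134 for subset by strain and 50 for the 3-way test. In the first 4 of these 5, 4, 2 and 4 of 6 arrays correlated best with their own number, a hint from the data and not the design. Over all comparisons the fixed block ended 5 list calls, added 11 and ended no call of a gene named. Where the numbers pair the arrays it changed no list call other than the 7 given under the processing. Of the 185 list shifts that passed, 28 passed with an estimated correlation, 128 with fry, 178 without the filter, 179 with mean probe sets, 173 with quantile normalization and 168 with median centring. Of 1596 fits of these lists with an array left out 1385 passed. In 129 the median moved by over 1.5 times, in 60 of the lists. Reversed medians were those of ribosomal proteins under median centring, -0.014 for strain by CpG and -0.021 for NOD against B6 after CpG in CD8+ cDC. With single arrays left out they were red pulp macrophage markers for subset by strain (-0.023 to 0.881), type I IFN-stimulated genes for subset by CpG in NOD (-0.042 to 0.285) and apoptosis genes for strain by CpG in CD11b+ cDC (-0.186 to 0.018). The genes named in the text kept their side of the threshold in 37244 fits over all comparisons, lost the call in 771, gained it in 624 and did not reverse while called. Signal over background limits the tests to 11228 of 19938 genes, and Ifnb1 is among those too dim.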

Other observations

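No explanation is offered in this part, and its genes and families were chosen after their values were seen. The Gimap genes, GTPases known from lymphocytes, rose in CD11b+ cDC of B6 mice after CpG for 7 of 7 (median 2.24), with Gimap4 at 2.98, Gimap7 at 2.97 and Gimap3 at 2.55, and the medians were 0.14, -0.19 and 0.03 in B6 CD8+, NOD CD8+ and NOD CD11b+ cDC. The interaction of strain with CpG passed for 5 of 7, among them Gimap3 (-2.83) and Gimap7 (-2.73). The NK receptor genes Klra3 (2.74) and Klra8 (2.83) rose in the same group, with interactions of -2.50 and -2.53.

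Of the 10 measured genes of the Ifi200 family, interferon-inducible genes some of which sense DNA, 4 were more induced in NOD than in B6 CD11b+ cDC, among them Ifi202b (4.29), Ifi208 (2.23) and Ifi207 (0.97). Under PBS Ifi206 (-2.14), Ifi213 (-2.08) and Ifi207 (-1.22) were lower in NOD CD11b+ cDC. Of 7 schlafen genes 7 rose in every comparison of CpG with PBS, and in NOD CD11b+ cDC Slfn5 was more (0.86) and Slfn4 less induced (-1.78). Members of these families share sequence, so single members are uncertain.

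The inflammasome sensor genes of the Nlrp1 family went opposite ways between strains. Nlrp1a was higher in NOD in all 4 comparisons (1.75 and 0.96 under PBS and 1.80 and 1.92 after CpG in CD8+ and CD11b+ cDC), whereas Nlrp1b (-2.15 and -1.23) and the pseudogene Nlrp1c-ps (-2.80 and -2.50) were lower under PBS. Nlrp1b fell with CpG in B6 CD8+ cDC (-1.97) and did not pass in NOD CD8+ cDC (-0.14), with an interaction of 1.83. Of 8 Clec4 genes 7 fell with CpG in B6 CD11b+ and 2 in NOD CD11b+ cDC, and 4 were higher in NOD after CpG, with Clec4a2 at 2.09. Of 25 replication-dependent histone genes 6 were lower in NOD CD8+ and 10 in NOD CD11b+ cDC under PBS, with medians of -0.32 and -0.39. Apol10b rose with CpG in B6 CD11b+ cDC (1.73) and did not pass in NOD (-0.09), with an interaction of -1.82.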
